A study of Mus musculus with 10 samples.

How the data were processed

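The series measured RNA on single-colour Agilent mouse arrays (Cy3) in 10 samples that fall into 5 groups of 2, as the sample labels give them. Muscle came from male C57BL/6J mice: untreated wild type, vehicle-injected hSA::Fv2E-PERK transgenic and AP20187-injected transgenic. C2C12 myoblasts carrying Fv2E-PERK were grown in 10% fetal bovine serum, differentiated in 2% horse serum for 3 days and given vehicle or AP20187. Mice received AP20187 at 1 ng/g and cells at 100 nM, and both were collected after 12 h. Per the labels' protocols, 150 ng of RNA was labelled for each array.

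Each array came as a scanner file with a spot intensity on a linear scale (gProcessedSignal), which is background-subtracted by Agilent Feature Extraction 10.7.1.1, per the file headers. A table of log2 values deposited by the authors held the same arrays. It had 55821 lines, of which 55681 matched a gene probe, and its differences between arrays correlated with those of the scanner intensities at r of 0.9998 or more. The scale of that table is therefore log2 and its direction is that of the scanner values, while the baseline on which it was centred stays unknown. Its column medians were -0.46 and -0.45 for wild type, -0.42 and -0.35 for transgenic vehicle, -0.37 and -0.58 for transgenic AP20187, 0.34 and 0.70 for C2C12 vehicle, and 0.80 and 0.78 for C2C12 AP20187.

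Every array had 62976 spots, of which 3671 were controls and were left out. The remaining 59305 spots carried 55681 probes. Spots with an outlier flag of Feature Extraction were left out, which removed 0.160% to 2.37% of gene spots per array, and spots of the same probe were averaged. The values tested were log2 of the processed intensity minus the 75th percentile of that array, so that all fold changes are relative to this scaling. The files gave accessions and no gene symbols. RefSeq accessions were matched without versions to a table of the GRCm38.p6 assembly, which was used for names only. In this way 26056 probes received 19752 symbols, of which 14482 had a single probe and 5270 had several, and 25521 of 26108 NM accessions matched. A further 29625 probes stayed without a symbol, 16194 of them described by a genomic interval. For a gene with several probes, the brightest probe by the mean over the 10 arrays was used. Probes with a value on every array were preferred, a refinement made after the data were seen. A gene was tested if its probe was well above background on both arrays of at least 1 group in the fit.

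Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), and a change was called at a Benjamini-Hochberg adjusted p under 0.05. The 6 muscle arrays formed the fit for the AP20187 comparison and for transgenic vehicle against wild type (3 residual degrees of freedom). The 4 C2C12 arrays formed another (2 residual degrees of freedom), and all 10 arrays formed the last for the difference between the AP20187 changes in muscle and in C2C12 (5 residual degrees of freedom). The comparisons, the gene lists, the named genes and most alternatives were fixed before the data were examined. Named in each comparison are the 8 largest rises and the 8 largest falls among called genes, leaving out clone and predicted-gene names, and the 4 members with the smallest p of each gene list that passed. Some genes that this rule picks are not reported here. In the AP20187 comparisons Eif2ak3, Atf4, Atf5, Ddit3, Trib3, Chac1, Asns, Psat1, Fgf21 and Gdf15 are named whatever their test, and for the difference between muscle and C2C12 the 6 largest in each direction.

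In all, 34 gene lists were tested with camera at a preset correlation of 0.01 between genes. They covered the integrated stress response, amino acid synthesis and transport, cytosolic and mitochondrial tRNA synthetases, ER chaperones, mitochondrial chaperones and proteases, heat shock proteins, NRF2 targets, translation factors, ribosomal proteins, autophagy, muscle atrophy, inflammation, interferon response, secreted factors, circadian clock, cell cycle, sterol synthesis, glycolysis, fatty acid oxidation, oxidative phosphorylation, fast and slow fibre genes, myogenic genes and denervation genes. Markers of macrophages, lymphocytes, endothelium, vascular smooth muscle, adipocytes, fibroblasts, Schwann cells and erythroid cells were included. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes, were the alternatives. P-values of lists were adjusted over the 34 lists of a comparison. Camera and fry used only members with a value on every array of the fit. For many lists in C2C12, and in the difference between muscle and C2C12, these were fewer than the measured members. Counts and medians cover all measured members. With an estimated correlation, camera has only the residual degrees of freedom of the fit (3, 2 or 5), so that few lists could pass. For the ISR list with AP20187 in muscle the estimated correlation was -0.027, yet the unadjusted camera p went from 1.94e-15 to 0.0031. Not passing with an estimated correlation is therefore no evidence that a list did not change.

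Where a gene was not well above background on any array of a group, its fold is given as a bound. The mean of the brighter group was set against the mean of the dimmer group, in which each array counted at the higher of its own value and the lowest signal of any probe well above background. Such folds are written "at least", and differences between muscle and C2C12 with groups put at this floor are named as such. These bounds hold for the background-subtracted values, and normexp, which compresses dim signals, gave smaller changes. They allow for missing signal but not for the spread between arrays, so that they are not lower confidence limits. Other folds are 2 to the power of the fitted log2 change.

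The tests were run on simulated data built from the real arrays, with genes changed by known folds. In the muscle AP20187 comparison 12 of 67 genes changed 1.5-fold, 42 of 67 changed 2-fold and 55 of 66 changed 4-fold were recovered, with 8 false calls. In C2C12 the recovered numbers were 14, 41 and 58, with 4 false calls. In transgenic vehicle against wild type they were 12, 43 and 56, with 5 false calls, and for the difference between muscle and C2C12 they were 7, 44 and 57, with 4 false calls. A simulated list of 20 genes raised 1.5-fold was found by camera in each of the 4 comparisons, and with an estimated correlation in the muscle AP20187 comparison alone. The simulated genes took the means and spread of the real ones but were drawn independently of each other. The simulation so cannot tell how camera behaves for correlated lists, such as ribosomal proteins in muscle (estimated correlation 0.78). Far fewer genes were changed than were called in muscle.

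Alternatives were normexp background correction, quantile normalization, the authors' log2 table, no filter on dim probes, a filter on every array, no variance trend, other sets of arrays in the fit, the replicate number as a block, the mean over the probes of a gene that have a value on all arrays, other thresholds and leaving out each array in turn. Normexp was run on the median spot signal in place of the mean signal that had been planned. Added after the data were seen were a percentile over the 17912 probes detected on every array, keeping outlier spots, testing probes without a symbol, random lists matched on mean signal, and differences with groups lacking signal put at the floor. Slides and scan sessions were read from the file headers. The slide identifier of the C2C12 arrays also occurs on the transgenic muscle arrays, so that sessions were told apart by identifier and scan time together, and which slide those arrays were on is in doubt. Wild type arrays were scanned in a session of their own, the transgenic muscle arrays of both treatments in another, and the C2C12 arrays of both treatments in the last.

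Between 41.0% and 53.1% of gene spots per array were well above background, and no spot was saturated. Replicates of a group correlated at r = 0.989 to 0.993 across genes, with a median absolute difference of 0.14 to 0.18 log2 units. With 2 arrays per group, the number of arrays limits the precision. The labels do not say whether the C2C12 replicates are separate cultures, so that p-values there measure the spread between these samples, which may be technical. Figures were drawn with matplotlib 3.10.9.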

Results

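Gene expression was measured in muscle and in cultured muscle cells that carry Fv2E-PERK, a fusion of the kinase PERK with a domain that pairs when the compound AP20187 binds it. PERK phosphorylates the translation factor eIF2alpha, which starts the integrated stress response (ISR). In the hSA::Fv2E-PERK mice a skeletal actin promoter drives the fusion in muscle, and the series title points to ISR targets there. The 10 arrays fall into 5 groups of 2: untreated wild type muscle, transgenic muscle after vehicle, transgenic muscle after AP20187, C2C12 Fv2E-PERK cells after vehicle and the same cells after AP20187. C2C12 is a mouse myoblast line that forms myotubes in low serum. Gene spots well above background made up 51.8% and 53.1% on the wild type arrays, 49.1% and 49.0% on transgenic vehicle, 46.6% and 48.8% on transgenic AP20187, 52.4% and 41.0% on C2C12 vehicle, and 44.5% and 43.7% on C2C12 AP20187.

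Eif2ak3, the gene for PERK, was measured on every array. Its level, in log2 units relative to the 75th percentile of the array, was -1.31 ± 0.06 (SD, n = 2) in wild type muscle, -1.11 ± 0.17 in transgenic vehicle and -1.02 ± 0.15 in transgenic AP20187. In C2C12 it was 0.28 ± 0.15 after vehicle and 0.04 ± 0.14 after AP20187. No comparison passed the test: the log2 change was 0.20 (SE 0.16) in transgenic vehicle against wild type, 0.09 (SE 0.16) with AP20187 in muscle and -0.25 (SE 0.16) in C2C12, with adjusted p of 0.362, 0.711 and 0.523. Whether the probe lies in the part of PERK that the fusion holds is not given in the sources used here, so that it does not check the labels.

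**Figure D1:**
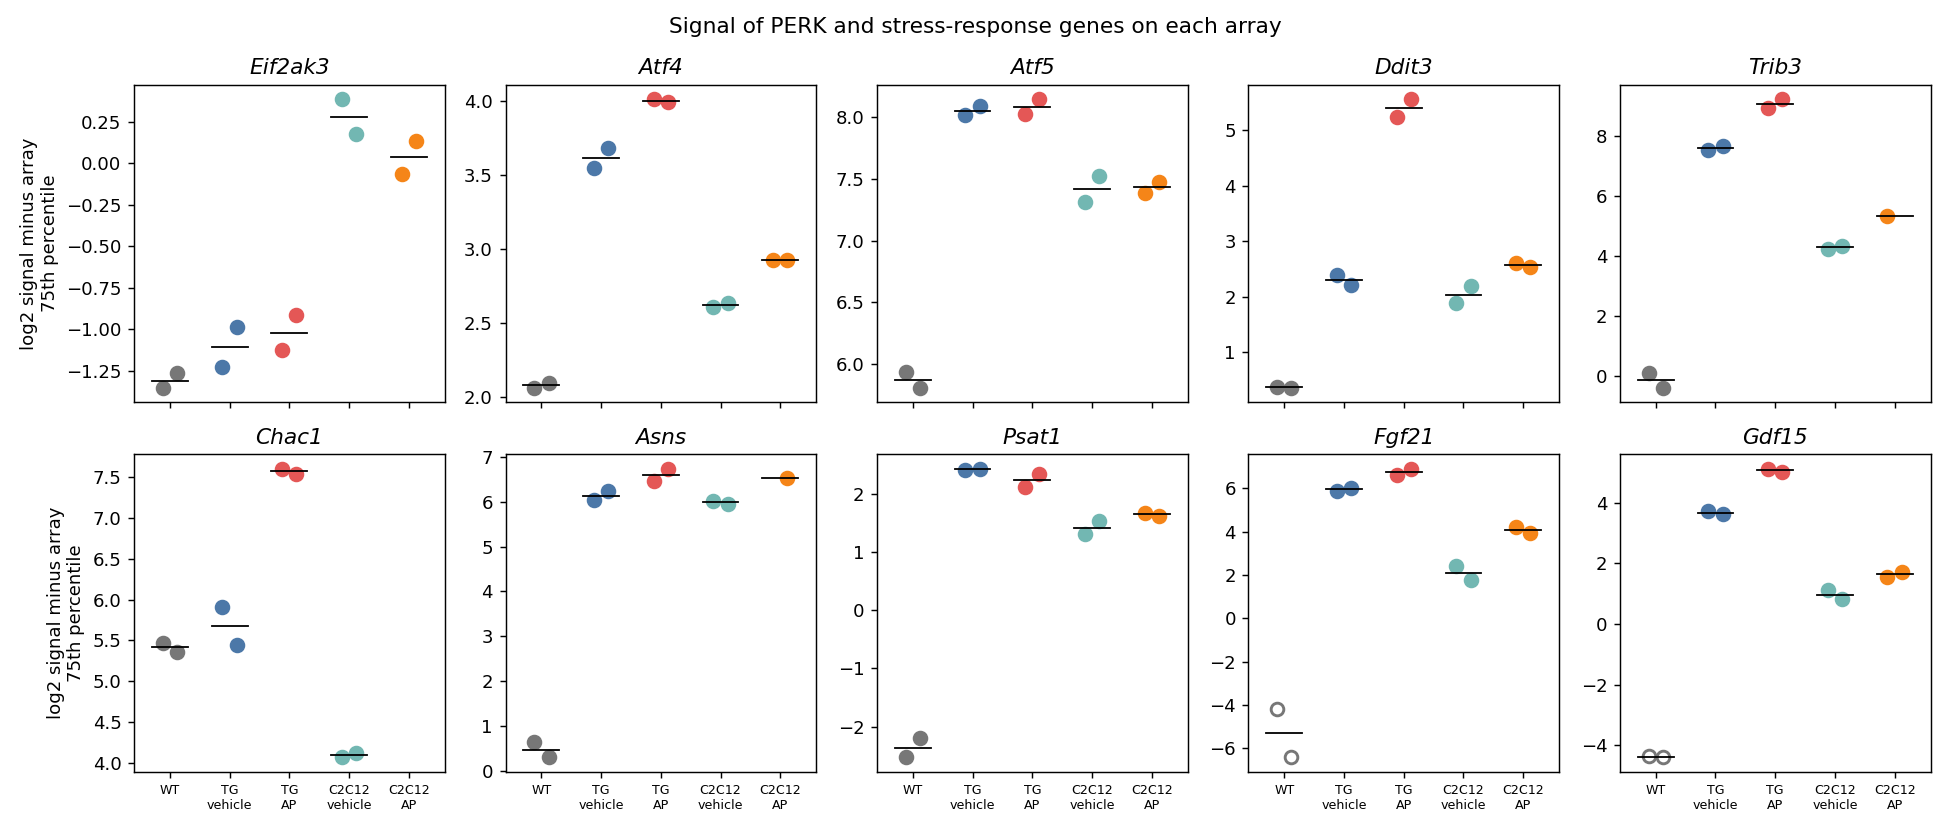
Each panel shows a gene named in advance, with log2 signal relative to the 75th percentile of the array on the vertical axis, a point for each array (open where not well above background) and a line at the group mean. Ddit3 rose by 3.09 log2 units with AP20187 in muscle, while Fgf21 was not well above background on either wild type array.

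In muscle of transgenic mice, 12 h of AP20187 raised Myc, the stress response regulator Ppp1r15a and the small nucleolar RNA host genes Snhg16, Snhg12 and Snhg1. The largest rises among named transcripts were Snhg16 (26.8-fold, log2 change 4.74 (SE 0.34)), the transcription factor gene Myc (22.6-fold, 4.50 (SE 0.21)), Bpifb3 (at least 4.95-fold), and Ppp1r15a (16.1-fold, 4.01 (SE 0.12)), whose product directs the dephosphorylation of eIF2alpha. They were followed by Snhg12 (14.2-fold), Snhg1 (14.0-fold), the clock repressor gene Ciart (13.1-fold) and the immediate early gene Fos (11.9-fold). Tfrc, the transferrin receptor, was 6.44-fold lower, the kinesin gene Kif5c 6.26-fold lower and the nicotinamide riboside kinase gene Nmrk2 5.59-fold lower. The other large falls were bounds: Neurog3 (at least 6.90-fold), Rgs9bp (at least 3.17-fold), Olfr48 (at least 2.97-fold), Cyp1a1 (at least 2.71-fold) and Ces2c (at least 2.14-fold). Neurog3 (mean log2 level -5.46 in wild type, -1.80 after vehicle and -5.80 after AP20187) and Kif5c (-2.55, -0.57 and -3.22) fell from vehicle means above wild type. Their vehicle arrays spread widely (SD 1.01 and 1.32), and Neurog3 lacked signal in wild type too. For each of the 16 genes named here, both AP20187 arrays lay on the same side of both vehicle arrays. They were picked by a test on these arrays, so that this adds no support.

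The ISR list, which holds regulators and classical targets of ATF4 and CHOP, rose: 18 of 23 measured members were higher, 0 were lower and 5 did not pass, and 19 were higher when adjusted over the list alone. The median log2 change was 1.22 (1.14 with the member that has only a bound put at it), with a camera adjusted p of 6.60e-14 and an adjusted p = 0.106 with an estimated correlation. Besides Ppp1r15a, the members with the smallest p were Atf3 (11.0-fold), Ddit3, which encodes CHOP (8.54-fold, log2 change 3.09 (SE 0.13)), and the apoptosis gene Bbc3 (5.66-fold). Trib3, a pseudokinase gene induced by ATF4 and CHOP, rose 2.79-fold, Chac1 3.71-fold and the cytokine gene Gdf15 2.64-fold. Atf4 itself rose by 0.39 (adjusted p = 0.0191) and the asparagine synthetase gene Asns by 0.47 (adjusted p = 0.0484). Atf5 had a log2 change of 0.03 (SE 0.10) and an adjusted p of 0.823 (0.26 after quantile normalization, where it passed), and Psat1 of -0.19 (SE 0.14) and 0.345. Fgf21, which encodes a secreted metabolic hormone, had a log2 change of 0.80 (SE 0.58) and an adjusted p of 0.321. It passed with normexp, without wild type replicate 1 or 2, and when the fit held the 4 transgenic arrays alone.

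Other groups that rose held fewer called members. Amino acid transporter genes were higher in 9 of 22 and lower in 1 (10 and 1 adjusted over the list alone; median log2 change 0.38, camera adjusted p = 0.000462, adjusted p = 0.364 with an estimated correlation). Its leading members were the glycine transporter Slc6a9 (2.61-fold), the glutamine transporter Slc38a3 (2.07-fold), the cationic transporter Slc7a1 (2.22-fold) and the heavy chain Slc3a2 (2.06-fold). Cytosolic tRNA synthetase genes were higher in 5 of 20 and lower in 0 (7 higher adjusted over the list alone), led by Lars, Tars, Aars and Iars with log2 changes of 0.81, 0.99, 0.58 and 0.43. For that list the median was 0.20, the camera adjusted p = 0.00725 and the adjusted p = 0.609 with an estimated correlation. Of the atrophy list, 9 of 21 rose (10 and 1 lower adjusted over the list alone), among them the transcription factor gene Klf15 (2.74-fold), the ubiquitin ligase gene Trim63 (1.74-fold) and the metallothionein gene Mt2 (2.23-fold). Its median was 0.32, with a camera adjusted p of 0.00704 and an adjusted p = 0.359 with an estimated correlation. Trim63 (mean log2 level 6.29 in wild type, 5.17 after vehicle and 5.97 after AP20187) and Slc38a3 (1.80, 0.93 and 1.98) rose from vehicle means below wild type. Inflammation genes rose in 7 of 18 and fell in 1 (8 and 2 adjusted over the list alone). The named members, Fos, Relb (2.82-fold), Egr1 (7.06-fold) and Nfkbia (1.73-fold), are immediate early or NF-kappaB pathway genes rather than cytokines, and the list had a median of 0.58, a camera adjusted p of 0.00549 and an adjusted p = 0.359 with an estimated correlation.

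Clock genes were higher in 7 of 17 members and lower in 0, with the same 7 calls in number when adjusted over the list alone. The median log2 change was 0.41, the camera adjusted p = 0.000186 and the adjusted p = 0.345 with an estimated correlation. Per2 rose at least 3.71-fold, Ciart 13.1-fold, Nfil3 4.05-fold and Cry2 1.99-fold.

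Though none passed with an estimated correlation, the macrophage and fibroblast lists fell with AP20187 by camera, as did oxidative phosphorylation and fast fibre genes, though the latter lists did not pass after quantile normalization. Macrophage and leucocyte markers were lower in 14 of 16 and higher in 0 (15 lower adjusted over the list alone), among them the complement genes C1qa (1.97-fold lower) and C1qc (1.85-fold), Fcer1g (1.88-fold) and Cd74 (2.02-fold). The median was -0.92, the camera adjusted p = 3.55e-07 and the adjusted p = 0.450 with an estimated correlation. Fibroblast and matrix markers fell in 7 of 19 (8 adjusted over the list alone), with the tendon transcription factor gene Scx 2.09-fold lower and Tnmd, Mfap5 and Lum at log2 changes of -0.47, -0.37 and -0.45 (median -0.33, camera adjusted p = 0.00844, adjusted p = 0.609 with an estimated correlation). Oxidative phosphorylation genes fell in 20 of 46 (32 adjusted over the list alone), for example Ndufb3 by 1.72-fold, Atp5g3 by 1.56-fold, Sdhc by 1.47-fold and Ndufa5 by 1.45-fold. The camera adjusted p of this list was 6.95e-07 at a median of -0.32, with an adjusted p = 0.609 with an estimated correlation and 0.0646 after quantile normalization. Fast fibre genes fell in 6 of 19 (10 adjusted over the list alone), with the muscle phosphoglycerate mutase gene Pgam2 2.12-fold, the parvalbumin gene Pvalb 1.85-fold, the calsequestrin gene Casq1 1.55-fold and the myosin light chain gene Mylpf 1.43-fold lower. The median of -0.32 (camera adjusted p = 0.00307, adjusted p = 0.688 with an estimated correlation) turned to 0.01 after quantile normalization, where the camera adjusted p was 0.415.

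Ribosomal protein genes had a median log2 change of -0.27 with AP20187, with 10 of 42 members lower, 0 higher and 0 lower when adjusted over the list alone. Rpl24, Rpl6, Rpl11 and Rpl27 had log2 changes of -0.50, -0.37, -0.54 and -0.39, and Rpl6 turned to 0.04 when the mean over its probes was used, which includes a dim probe, while its 3 probes well above background ranged from -0.37 to -0.27. The camera adjusted p was 0.000186, with an adjusted p = 0.688 with an estimated correlation and 0.718 after quantile normalization. Markers of adipocytes (median -0.50, camera adjusted p = 0.311), lymphocytes (-0.37, 0.133), erythroid cells (-0.48, 0.153), Schwann cells (-0.37, 0.187), endothelium (0.07, 0.639) and vascular smooth muscle (-0.01, 0.724) did not pass. Heat shock genes (-0.28, 0.187), mitochondrial tRNA synthetases (0.10, 0.187), glycolysis (-0.17, 0.447), interferon genes (0.12, 0.520) and secreted factors (-0.11, 0.724) did not pass either. ER chaperone genes rose in 9 and fell in 2 of 33, and the list missed the threshold (median 0.01, camera adjusted p = 0.0974). Median and mean or test differed in sign for NRF2 targets (median -0.19, mean 0.09), endothelium (mean -0.06), vascular smooth muscle (mean 0.00) and myogenic genes (mean 0.00), none of which passed.

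By limma, 3964 of 13543 genes tested in muscle (29.3%) changed with AP20187, 1937 higher and 2027 lower, of which 446 and 271 changed at least 2-fold. After quantile normalization the split was 2025 higher and 1275 lower. Leaving out vehicle replicate 2 left 1802 genes, and leaving out AP20187 replicate 1 or 2 left 2360 or 2592. Of the 34 lists 11 passed, 10 passed with fry and 0 with an estimated correlation, for which 4 had an unadjusted p under 0.05. Camera and fry both passed 7 lists in the same direction. Both treatments were scanned in the same session, and the 4 arrays of that session alone gave 3360 genes. Of the 62 called genes that the naming rule picks, 46 kept their call under every alternative that gave them a value, and Ciart, Ces2c, Rgs9bp, Olfr48, Atf4, Asns, Ndufa5, Rpl24, Rpl6, Rpl11, Rpl27, Aars, Iars, Tnmd, Mfap5 and Lum lost it under at least 1. With normexp the log2 change shrank by more than 1.5 times for 10 of them, among them Bpifb3 (0.84), Neurog3 (-0.82), Per2 (0.68), Olfr48 (-0.57), Cyp1a1 (-0.56), Ces2c (-0.43) and Rgs9bp (-0.38), so that the folds written as at least hold for the background-subtracted values alone. Kif5c went to -1.16 with normexp and to -1.72 without vehicle replicate 1, Olfr48 to -1.48 without AP20187 replicate 1, and Snhg16 to 2.99 with the mean over its probes. After quantile normalization 10 shrank as much, such as Pvalb (-0.45).

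**Figure D2:**
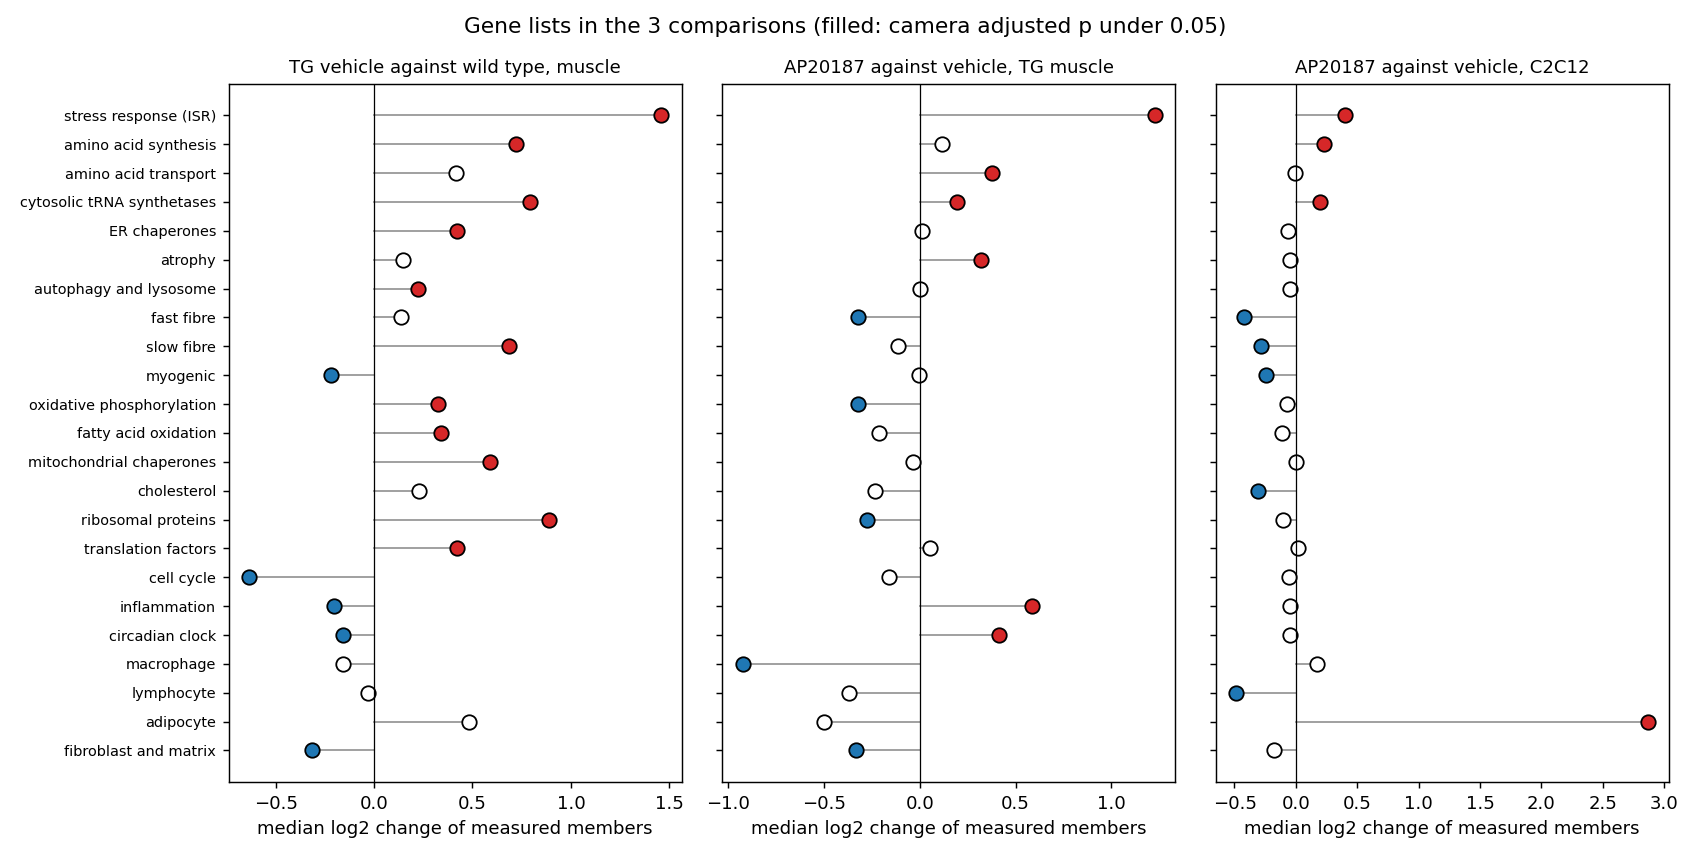
Median log2 change of the measured members (horizontal axis) of each gene list that passed in at least 1 of the 3 comparisons, filled where the camera adjusted p was under 0.05 (red for higher, blue for lower). The ISR list lies at 1.46, 1.22 and 0.40 from left to right, and the adipocyte list at 2.87 in C2C12. Oxidative phosphorylation turned to -0.15 in the left panel after quantile normalization, and fast fibre to 0.01 in the middle panel.

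In C2C12 cells, genes typical of fat cells were higher after AP20187 and genes of the mature fast fibre lower, beside a smaller rise of ISR genes, all 3 by camera. None of these lists passed with an estimated correlation (adjusted p = 0.297, 0.324 and 0.297). Vehicle and AP20187 arrays lay in different slide rows, and 0 rows held both, so that row and treatment cannot be told apart for any C2C12 change. Thrsp, a lipogenic regulator, rose at least 7.80-fold, the fatty acid binding protein gene Fabp4 by 3.70 (SE 0.23) log2 units, the adipsin gene Cfd 12.9-fold, the adiponectin gene Adipoq at least 7.88-fold, the resistin gene Retn 9.37-fold and the lipoprotein lipase gene Lpl 6.96-fold. Crmp1 rose at least 5.20-fold and Glrp1 5.79-fold. The largest falls were in the tubulin gene Tuba8 (at least 8.03-fold), the fast myosin binding protein gene Mybpc2 (at least 8.14-fold), the sarcomeric mitochondrial creatine kinase gene Ckmt2 (at least 5.13-fold) and Pvalb (7.54-fold, log2 change -2.91 (SE 0.15)). They were followed by the fast myosin gene Myh4 (3.56-fold), Rasa4 (2.64-fold), the telethonin gene Tcap (2.48-fold) and Pgam2 (2.14-fold). Both AP20187 arrays lay on the same side of both vehicle arrays for each of these 16 genes, which adds no support, since a test on these arrays picked them.

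Adipocyte markers were higher in 6 of 11 measured members and lower in 0 (8 and 1 adjusted over the list alone). Their median log2 change was 2.87, or 1.89 with the 4 members that have only a bound put at it (camera adjusted p = 1.21e-17, adjusted p = 0.297 with an estimated correlation). Fast fibre genes fell in 4 of 17 (10 adjusted over the list alone) with a median of -0.42. Over the 13 of them with a value on every array, the camera adjusted p was 2.83e-13 (adjusted p = 0.324 with an estimated correlation). Slow fibre genes (median -0.28, camera adjusted p = 0.000228, adjusted p = 0.324 with an estimated correlation) had Ckmt2 as the only call among 13 over all genes and 1 adjusted over the list alone. In that list Myl2, Casq2 and Myh7 had log2 changes of -1.05, -0.30 and -0.38 without passing. Myogenic genes had 0 and 0 calls of 18 by limma, 1 higher and 6 lower adjusted over the list alone (median -0.24, camera adjusted p = 0.00676, adjusted p = 0.415 with an estimated correlation). Their leading members Sgca, Neb and Jph2 stood at -0.64, -0.50 and -0.47, and Jph1 at 0.90.

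The ISR list rose in C2C12 with a median log2 change of 0.40: 3 of 19 measured members were higher, 0 lower and 16 did not pass, and 11 were higher adjusted over the list alone. Over the 18 members with a value on every array, the camera adjusted p was 6.18e-11, with an adjusted p = 0.297 with an estimated correlation. Atf3 rose 2.71-fold and Gadd45a 2.24-fold, while Nupr1 had a log2 change of 0.65 and an adjusted p of 0.0778. Fgf21 rose 3.97-fold (log2 change 1.99 (SE 0.19), adjusted p = 0.000336). The other genes named in advance did not pass: Ddit3 had a log2 change of 0.54 (adjusted p = 0.124), Gdf15 0.67 (0.0777), Asns 0.54 (0.165), Atf4 0.30 (0.286), Psat1 0.23 (0.471) and Atf5 0.02 (0.971). Gdf15 and Nupr1 each passed under 6 alternatives, among them quantile normalization, no filter on dim probes and the percentile over detected probes. The spots of Chac1 carried outlier flags on both AP20187 arrays and those of Trib3 and Asns on 1 each. The log2 change of 1.04 for Trib3, which passed, and that of Asns so rest on 1 AP20187 array, with the spread taken from the vehicle arrays and other genes. With these spots kept, Chac1 rose by 0.78 (adjusted p = 0.0124), while Trib3 at 0.78 (0.0510) and Asns at 0.50 did not pass.

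Amino acid synthesis genes rose in 2 of 23 (9 higher and 2 lower adjusted over the list alone): the cystathionine gamma-lyase gene Cth 2.56-fold and the phosphoserine phosphatase gene Psph 1.65-fold. In the same list Mthfd2 (0.65) and Glul (-0.61) did not pass, and the median was 0.23 (camera adjusted p = 0.00157, adjusted p = 0.324 with an estimated correlation, 0.129 after normexp). Cytosolic tRNA synthetases had 0 calls of 18 by limma and 4 adjusted over the list alone, with Tars, Eprs, Yars and Lars at log2 changes of 0.58, 0.63, 0.63 and 0.45 (median 0.20, camera adjusted p = 0.00434, adjusted p = 0.340 with an estimated correlation, 0.210 after normexp). Sterol genes fell as a list (median -0.31, camera adjusted p = 1.67e-06, adjusted p = 0.324 with an estimated correlation, both tests over 22 members), with 1 of 24 called over all genes and 9 adjusted over the list alone. The call was Mvd (1.71-fold lower), and Pmvk and Ebp had log2 changes of -0.59 and -0.50. Of lymphocyte markers 3 were measured (Cd4 -0.51, Nkg7 -0.49, Cd3e -0.18), with 0 called over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.0354, adjusted p = 0.433 with an estimated correlation, 0.170 after normexp).

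By limma, 55 of 11409 genes tested in C2C12 passed (0.482%), 36 higher and 19 lower, while 1616 had an unadjusted p under 0.05. The count was 360 after normexp (162 higher, 198 lower), 84 with the percentile over detected probes (67 higher, 17 lower), 306 without vehicle replicate 1, 26 without vehicle replicate 2, 203 without AP20187 replicate 2, and 51 higher and 56 lower without AP20187 replicate 1. A further 205 genes had no value on a group because their spots carried outlier flags, and the AP20187 arrays carried 1271 and 1050 non-uniform spots against 89 and 41 with vehicle. Of the lists 9 passed, 11 with fry and 0 with an estimated correlation, for which 5 had an unadjusted p under 0.05. Both camera and fry passed 8 lists in the same direction, and the myogenic list did not pass with fry (adjusted p = 0.122). Median and mean or test differed in sign for secreted factors (mean 0.12), amino acid transport (0.06), inflammation (0.04), translation factors (-0.02) and fatty acid oxidation (0.05), none of which passed. Among 23 called named genes, Lpl, Mybpc2, Rasa4, Tcap, Pgam2, Trib3, Fgf21, Gadd45a, Mvd, Cth and Psph lost the call under at least 1 alternative. Of the named genes that did not pass, Mthfd2 passed under 7 alternatives, Tars and Sgca under 6 each, Pmvk under 4, Ebp under 2, and Glul, Eprs, Neb, Jph1 and Cd4 under 1 each. Fabp4, Cfd, Retn, Lpl and Glrp1 were well above background on 1 of the 2 vehicle arrays. With normexp the log2 change shrank by more than 1.5 times for 11 of the 23, to 2.45 for Fabp4, 2.42 for Cfd, 2.10 for Thrsp, 1.77 for Adipoq, 1.57 for Lpl, -1.42 for Tuba8, -1.39 for Mybpc2 and -1.07 for Ckmt2, and that of Retn to 0.497 of its value.

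Whether AP20187 acted alike in muscle and in C2C12 was tested through the difference between the 2 changes. Snhg16 (difference in log2 change 4.27 (SE 0.40)), Myc (4.19), Fos (3.71) and Ppp1r15a (3.44) had a higher change in muscle, as had Tuba8 (at least 2.76) and Mybpc2 (at least 2.96), which fell in C2C12. A lower change in muscle was seen for Retn (-4.16), Cfd (-4.05) and Fabp4 (-3.85), and, with groups lacking signal put at the floor, for Thrsp (-3.80), Adipoq (-3.56) and the defensin gene Defa31 (-2.85). With normexp 7 of the 14 called differences shrank by more than 1.5 times, such as Tuba8 (1.28), Mybpc2 (1.37), Defa31 (-1.52) and Retn (-2.40), and Snhg16 went to 2.71 with the mean over its probes. Among the genes named in advance, Ddit3 (2.56 (SE 0.19), adjusted p = 1.71e-05) and Gdf15 (0.72 (SE 0.18), adjusted p = 0.0179) had a higher change in muscle. The call of Gdf15 was lost without transgenic vehicle replicate 2, transgenic AP20187 replicate 1, C2C12 vehicle replicate 1 or C2C12 AP20187 replicate 1. No difference passed for Trib3 (0.44 (SE 0.25)), Psat1 (-0.41 (SE 0.20)), Fgf21 (-1.19 (SE 0.69)), Eif2ak3 (0.33 (SE 0.24)), Atf4 (0.08 (SE 0.14)), Atf5 (0.02 (SE 0.15)) or Asns (-0.08 (SE 0.22)), which leaves differences of about 2 standard errors either way open. The difference for Fgf21 passed with normexp and without either wild type array, that for Atf4 with normexp and that for Psat1 with outlier spots kept.

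As a group, ISR genes had a higher change in muscle, with 10 of 19 members called (median difference 0.72, camera adjusted p = 7.27e-07, adjusted p = 0.0661 with an estimated correlation), and 10 adjusted over the list alone. Adipocyte markers had a lower change, with 8 of 11 called, 8 adjusted over the list alone (median -3.51, or -2.84 with the 4 members that lack signal in a group put at the floor, camera adjusted p = 7.70e-08, adjusted p = 0.242 with an estimated correlation). Clock (median 0.55), amino acid transport (0.46), inflammation (0.39) and denervation genes (0.23) differed upward with camera adjusted p of 0.0220, 0.0295, 0.0304 and 0.0489 (adjusted p = 0.242, 0.297, 0.242 and 0.242 with an estimated correlation). Oxidative phosphorylation (-0.26), ribosomal protein (-0.20), macrophage (-0.74), erythroid (-1.43) and fatty acid oxidation genes (-0.20) differed downward with camera adjusted p of 0.000203, 0.0124, 0.0124, 0.0326 and 0.0489 (adjusted p = 0.638, 0.753, 0.242, 0.242 and 0.595 with an estimated correlation). Only 5 macrophage members (2 called) and 3 erythroid members (1 called) were measured, and the erythroid median in C2C12 was 1.06. The list tests used 30 of 40 measured oxidative phosphorylation members and 31 of 38 ribosomal protein members, those with a value on every array. With fry, oxidative phosphorylation (adjusted p = 0.0883), ribosomal protein (0.318) and fatty acid oxidation genes (0.0991) did not pass. By camera, amino acid transport (0.0779), ribosomal protein (0.233) and erythroid genes (0.149) did not pass after normexp, inflammation (0.0524) after quantile normalization and macrophage genes (0.0611) with outlier spots kept. Denervation genes did not pass after quantile normalization (0.0726) or with outlier spots kept (0.0611), nor fatty acid oxidation genes after quantile normalization (0.176), normexp (0.0781) or with outlier spots kept (0.0576). Interferon, amino acid synthesis and translation factor genes, which did not pass, had medians (0.08, -0.08, -0.02) that differed in sign from the mean or the test. By limma 1790 of 10663 genes differed (16.8%), 1279 upward and 511 downward, and 1082 without transgenic vehicle replicate 2 or 1147 without C2C12 AP20187 replicate 1. Tissue and cells were scanned in separate sessions, and a session effect common to both treatments cancels in this difference. An effect of slide row does not cancel, since 0 slide rows held both C2C12 treatments. Dose, route and system differ together between muscle and C2C12, so that the difference cannot be assigned to any of them.

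Few genes were called in both systems. Among 10658 genes tested in both, 8 were higher in both (independent lists would share 4.54): Atf3, Cdsn, Cth, Dgat2, Extl1, Fut1, Gadd45a and Trib3. The C2C12 call of Trib3 rests on 1 AP20187 array and was lost with outlier spots kept (adjusted p = 0.0510). Dvl3, Pgam2 and Pvalb were lower in both (2.80 for independent lists). Ccdc134, Mvd and Rasa4 were higher in muscle and lower in C2C12 (3.20), and Cyp2e1 was lower in muscle and higher in C2C12 (3.97), small sets whose members were named after their values were seen. The 11 genes of like direction became 55 after normexp, 7 without transgenic vehicle replicate 2 or C2C12 vehicle replicate 2, and 42 without C2C12 vehicle replicate 1. Across genes, which are not independent replicates, the changes in muscle and in C2C12 correlated at r = 0.0046 (Spearman's rho 0.028), and across the 19 ISR genes measured in both at r = 0.38 (rho 0.44).

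**Figure D3:**
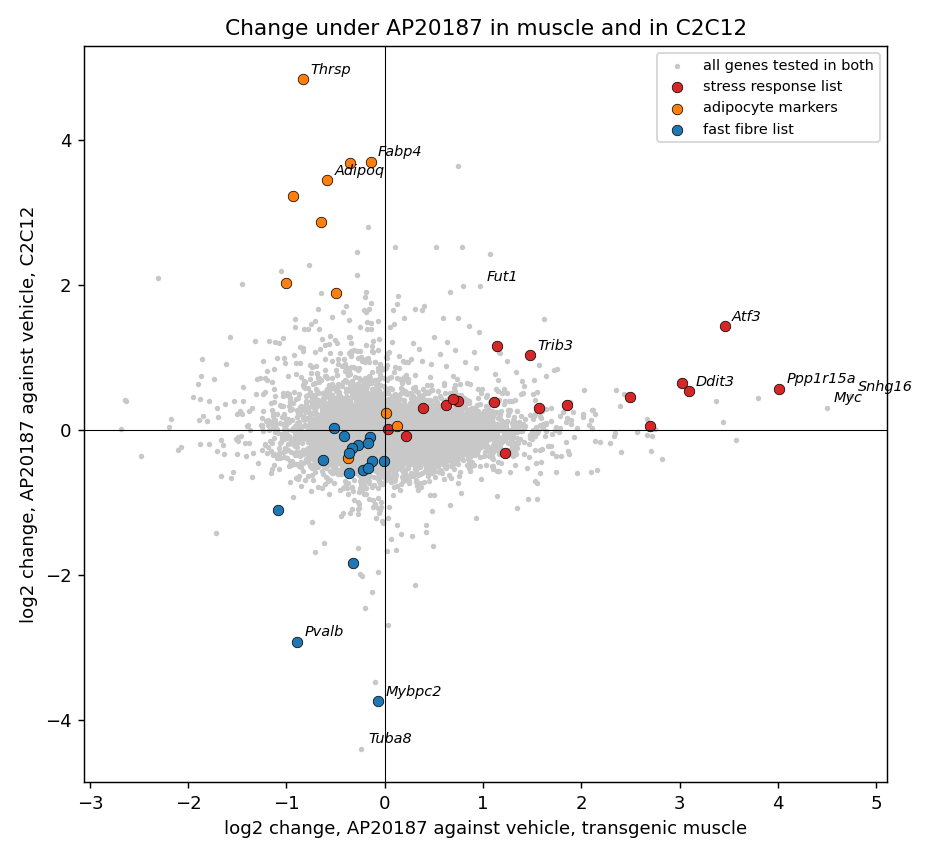
Log2 change with AP20187 in transgenic muscle (horizontal axis) against that in C2C12 (vertical axis) for the 10658 genes tested in both, with a point for each gene. ISR genes lie to the right, with Ppp1r15a at 4.01 and 0.58, and adipocyte markers at the top, with Fabp4 at -0.14 and 3.70. Fast fibre genes lie to the left and below 0, where the median in muscle turned to 0.01 after quantile normalization.

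Before any AP20187, muscle of vehicle-injected transgenic mice already differed widely from untreated wild type. The hormone gene Fgf21 was higher by at least 1163-fold, Gdf15 by at least 249-fold, the sterol acyltransferase gene Soat2 by at least 219.8-fold, Trib3 by 215-fold (log2 change 7.75 (SE 0.17)), and the cationic amino acid transporter gene Slc7a3 by at least 74.6-fold. Nacad rose at least 63.7-fold, the fucosyltransferase gene Fut1 at least 49.7-fold and the peptide gene Adm2 at least 26.4-fold. The falls were led by Odf3l2 (24.1-fold), Mss51 (23.8-fold), the spermine oxidase gene Smox (14.9-fold) and, as bounds, the antitrypsin gene Serpina1a (at least 24.9-fold), the protease gene Htra4 (at least 11.1-fold), Fgfbp1 (at least 7.95-fold), the syntaphilin gene Snph (at least 7.15-fold) and Lrtm2 (at least 4.98-fold). The bound of Serpina1a leaves out the wide spread of its wild type arrays (SD 3.00), with which the 95% confidence interval of the fitted fold reached down to 4.38. Both arrays of each group lay apart for each of these 16 genes, which adds no support, since a test on the same arrays picked them.

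Enzymes of amino acid synthesis rose in 16 of 25 and fell in 2, 16 and 2 adjusted over the list alone. The list had a median of 0.72, a camera adjusted p of 6.21e-05 and an adjusted p = 0.254 with an estimated correlation. Asns rose 50.5-fold, the mitochondrial folate enzyme gene Mthfd2 41.9-fold, the phosphoserine aminotransferase gene Psat1 27.9-fold and the proline pathway gene Aldh18a1 11.8-fold. ISR genes rose in 14 of 23 and fell in 2, likewise 14 and 2 adjusted over the list alone (median 1.46, camera adjusted p = 9.17e-05, adjusted p = 0.254 with an estimated correlation). Sesn2 rose 5.65-fold, the translation repressor gene Eif4ebp1 4.88-fold and Atf5 4.53-fold. Cytosolic tRNA synthetases were higher in 19 of 20 (20 adjusted over the list alone), with Gars 3.28-fold, Eprs 3.09-fold, Lars 2.41-fold and Mars1 2.38-fold higher (median 0.79, camera adjusted p = 1.84e-07, adjusted p = 0.326 with an estimated correlation).

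Genes of protein synthesis and folding rose as well by camera, though none of these lists passed with an estimated correlation. Ribosomal protein genes were higher in 42 of 42 members, as many as adjusted over the list alone, with Rps19 2.49-fold, Rpl27 2.27-fold and Rpl23 2.05-fold higher. Their median was 0.89, or 0.38 after quantile normalization (camera adjusted p = 3.38e-16, adjusted p = 0.538 with an estimated correlation). Translation factors rose in 17 of 27 and fell in 1 (17 and 3 adjusted over the list alone), led by Eef1a1 (4.34-fold), Eif3c (3.08-fold), Eef1b2 (1.80-fold) and Eif2b3 (1.75-fold) (median 0.42, camera adjusted p = 0.00202, adjusted p = 0.326 with an estimated correlation, 0.0658 after quantile normalization). Mitochondrial chaperones and proteases rose in 16 of 17, the same number adjusted over the list alone, with Hspa9 2.55-fold, Hspe1 2.52-fold, Phb 2.02-fold and Grpel1 1.84-fold (median 0.59, camera adjusted p = 1.00e-05, adjusted p = 0.326 with an estimated correlation). ER chaperone genes rose in 17 of 33 (20 higher and 1 lower adjusted over the list alone), among them Derl1 (2.59-fold), the BiP gene Hspa5 (1.93-fold), Manf (1.91-fold) and Herpud1 (1.77-fold), with a median of 0.42, a camera adjusted p of 0.000646 and an adjusted p = 0.254 with an estimated correlation. Autophagy genes rose in 11 of 28 and fell in 2 (13 and 2 adjusted over the list alone), with the cathepsin gene Ctsl 4.34-fold, Map1lc3a 2.24-fold higher, Gabarap at a log2 change of 0.59 and Ulk1 1.85-fold lower. That list had a median of 0.22, a camera adjusted p of 0.0427 and an adjusted p = 0.326 with an estimated correlation, and did not pass after quantile normalization (0.696), normexp (0.0518), the percentile over detected probes (0.103, median 0.02) or with outlier spots kept (0.0572).

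Genes of slow fibres and of fatty acid oxidation were higher by camera under the 75th percentile scaling, though not with an estimated correlation. Slow fibre genes rose in 9 of 15 and fell in 2, as many adjusted over the list alone, with Casq2 6.21-fold, Myoz2 2.27-fold, Tpm3 1.80-fold and Tnnt1 1.74-fold higher (median 0.68, camera adjusted p = 0.0341, adjusted p = 0.625 with an estimated correlation, 0.339 after quantile normalization). Fast fibre genes went both ways, 4 higher and 7 lower of 19, with a median of 0.14, a mean of -0.07 and a camera adjusted p of 0.358 in the lower direction. Fatty acid oxidation genes rose in 17 of 30 and fell in 3 (17 and 4 adjusted over the list alone), led by Acot2 (7.45-fold), Fabp3 (2.06-fold), Acadl (1.87-fold) and Eci1 (1.68-fold) (median 0.34, camera adjusted p = 0.0214, adjusted p = 0.625 with an estimated correlation, 0.696 after quantile normalization). Oxidative phosphorylation genes were higher in 25 of 46 (27 adjusted over the list alone), such as Uqcrq, Ndufs8, Cox6a2 and Atp5h with log2 changes of 0.97, 0.71, 0.66 and 0.64. Their median of 0.33 (camera adjusted p = 0.000331, adjusted p = 0.625 with an estimated correlation) turned to -0.15 after quantile normalization, where the list passed in the lower direction (camera adjusted p = 0.0421). In that setting it did not pass with an estimated correlation (adjusted p = 0.804) or with fry (0.112).

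Cell cycle genes fell in 15 of 24 and rose in 5, the same numbers adjusted over the list alone. The median was -0.63, or -0.49 with the 6 members that have only a bound put at it (camera adjusted p = 0.000298, adjusted p = 0.326 with an estimated correlation). The kinase gene Aurka was 3.71-fold, Birc5 3.08-fold, the cyclin gene Ccnb2 at least 8.64-fold and Plk1 at least 4.36-fold lower. Myogenic genes fell in 10 and rose in 6 of 25 (11 and 6 adjusted over the list alone), with the cardiac actin gene Actc1 9.04-fold, the regulator gene Myod1 2.41-fold, Mybph 2.11-fold and the titin gene Ttn 3.00-fold lower (median -0.22, camera adjusted p = 0.0175, adjusted p = 0.625 with an estimated correlation). The 4 probes of Ttn ranged from -1.59 to 0.09. Clock genes fell in 6 and rose in 4 of 17, as many adjusted over the list alone, with Hlf 4.72-fold, Dbp 2.20-fold, Bhlhe40 1.79-fold and Per2 at least 2.65-fold lower (median -0.16, camera adjusted p = 0.0373, adjusted p = 0.326 with an estimated correlation, 0.0938 with the percentile over detected probes). Inflammation genes fell in 5 of 18, as many adjusted over the list alone: Fos 2.60-fold, Nfkbia 1.70-fold and Ccl5 1.62-fold, with Relb at -0.47 (median -0.20, camera adjusted p = 0.0427, adjusted p = 0.326 with an estimated correlation, 0.227 after quantile normalization). Per2, Fos, Nfkbia and Relb, lower here, were higher with AP20187, and both comparisons share the vehicle arrays, so that chance in those arrays moves them in opposite directions. The same limit applies to Trim63 and Slc38a3, and to Neurog3 and Kif5c, whose vehicle means lay above wild type and which fell with AP20187. It applies also to the medians of oxidative phosphorylation (0.33 here, -0.32 with AP20187) and ribosomal protein genes (0.89 and -0.27). Fibroblast and matrix markers fell in 6 of 19, as many adjusted over the list alone, with Thbs4 2.10-fold, Comp 1.77-fold, Fn1 1.56-fold and Pdgfra 1.55-fold lower (median -0.31, camera adjusted p = 0.0427, adjusted p = 0.625 with an estimated correlation). Macrophage markers had a median of -0.16 (camera adjusted p = 0.127), and for atrophy (median 0.15, mean -0.04) and erythroid genes (0.67, 0.33), which did not pass, the camera direction was the lower.

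By limma, 5184 of 13543 genes (38.3%) differed between transgenic vehicle and wild type muscle, 3478 higher and 1706 lower, and 642 and 490 by at least 2-fold. The split was 2676 higher and 2259 lower after quantile normalization, and 2059 and 2953 with the percentile over detected probes, which moved the median over all genes from 0.09 to -0.11. The count was 3116 and 3423 without wild type replicate 1 and 2, and 3278 without transgenic vehicle replicate 2. Of the 34 lists 16 passed, 20 with fry and 0 with an estimated correlation, for which 3 had an unadjusted p under 0.05. Both camera and fry passed 14 lists in the same direction. Myogenic and fibroblast genes did not pass with fry (adjusted p = 0.0947 and 0.124). Among the 79 called genes that the naming rule picks, Serpina1a, Atp5h, Tpm3, Tnnt1, Gabarap, Thbs4, Comp, Relb and Ccl5 lost the call under at least 1 alternative. With normexp the log2 change shrank by more than 1.5 times for 19 of the 79, among them Fgf21 (7.39), Gdf15 (4.92), Soat2 (4.81), Slc7a3 (3.65), Nacad (3.42), Fut1 (3.30), Adm2 (2.24), Htra4 (-1.66), Snph (-1.24), Fgfbp1 (-1.10), Lrtm2 (-1.04), Plk1 (-0.63) and Per2 (-0.56). Serpina1a, for which the wild type arrays differed widely, went to -2.57 without wild type replicate 2 and to -2.53 with normexp. After quantile normalization 14 shrank as much, such as Rpl23 (0.43) and Eci1 (0.29), and Tpm3 went to 0.24 with outlier spots kept. Genotype, injection and scan session differ together between these groups. Quantile normalization turned the oxidative phosphorylation median to -0.15, whereas Trib3 stayed between 7.15 and 8.00 and Asns between 5.18 and 5.83 under every alternative that gave them a value. For Trib3 and Asns alone, both strong rises, that argues against a session difference that keeps the order of genes within an array. A session difference that reorders genes stays open.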

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

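Each explanation below was set and tested after the results were seen. Across genes, 1279 had a higher AP20187 change in muscle than in C2C12 and 511 a lower change, by a test of that difference.

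Adipocyte genes rose in C2C12 with AP20187 (difference from muscle: list median -3.51, or -2.84 with groups lacking signal put at the floor; Retn -4.16, Cfd -4.05, Fabp4 -3.85, and Thrsp -5.67 and Adipoq -4.03, at the floor -3.80 and -3.56), but neither this difference nor the C2C12 median of 2.87 passed with an estimated correlation (adjusted p = 0.242 and 0.297). Whole muscle RNA in those arrays would raise fast fibre genes. Their median was -0.42 (SE 0.12), with 16 of 17 lower and 1 higher, which argues against it. A smaller share of differentiated muscle cells would lower fibre and myogenic genes by an amount that depends on the loss. Of these genes 45 of 48 were lower and 3 higher, with a median of -0.29 (SE 0.04). That median argues against a fall of 1 log2 unit or more, a size set after the results were seen, while a smaller loss stays open. Quantile normalization, which turned the sign of 1798 other genes, left the C2C12 median at 3.09 (SE 0.93). It keeps the order of genes within an array and so removes only signal differences that leave this order alike. The median argues against a difference of that kind between slide rows as the whole cause. A difference that reorders genes, such as those dim with vehicle, stays open. Array position acting on particular probes cannot be told apart from the treatment, since 0 slide rows held both C2C12 treatments.

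ISR genes were higher in vehicle-injected transgenic muscle than in wild type before AP20187 (median 1.46, adjusted p = 0.254 with an estimated correlation). Quantile normalization, which turned the sign of 1382 other genes, left the median at 1.22 (SE 0.46). That argues against a signal difference between scan sessions as the whole cause only if it leaves the order of genes within an array alike. A session difference acting on particular probes cannot be told apart from the transgene, since 0 sessions held both groups. Injection of the vehicle in place of the transgene stays open, since 0 arrays came from injected wild type or uninjected transgenic muscle.

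Clock genes were higher with AP20187 in muscle (adjusted p = 0.345 with an estimated correlation), and their change exceeded that in C2C12 by a median of 0.55. Sampling at another time of day was taken to raise the 5 measured output genes Dbp, Tef, Hlf, Nr1d1 and Nr1d2 as well. Clock genes peak at different hours, however, so that a shift in time need not raise them together. The median of these 5 output genes, 0.27 (SE 0.17), lay between the outcomes set for it. The test cannot decide on sampling time, and this explanation stays open.

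The AP20187 change was higher in muscle for Snhg16 (4.27, or 2.71 with the mean over its probes), Myc (4.19), Tuba8 (4.15, at the floor 2.76), Fos (3.71), Mybpc2 (3.67, at the floor 2.96), Ppp1r15a (3.44), Ddit3 (2.56) and Gdf15 (0.72), and lower for Defa31 (-4.41, at the floor -2.85). Among lists it was higher for ISR (0.72), amino acid transport (0.46), inflammation (0.39) and denervation (0.23). It was lower for oxidative phosphorylation (-0.26), ribosomal proteins (-0.20), macrophages (-0.74, 5 members measured), erythroid cells (-1.43, 3 members measured) and fatty acid oxidation (-0.20). None of these lists nor the adipocyte and clock lists passed with an estimated correlation (lowest adjusted p = 0.0661, for ISR), and by camera amino acid transport, ribosomal proteins, erythroid cells, inflammation, macrophages, denervation and fatty acid oxidation were lost under at least 1 other scaling or with outlier spots kept. Among 10707 probes without a gene symbol, which the comparisons leave out, 206 were higher and 505 lower with AP20187 in muscle, and 1801 were higher and 1674 lower in transgenic vehicle against wild type.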

How the results depend on the processing

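The percentile over detected probes, the outlier spots kept, the probes without a symbol, the matched random lists and the differences at the floor were chosen only after the results were seen.

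The C2C12 count varied widely, and the cause was not tested. From 55 it went to 360 with normexp, 137 without a filter on dim probes, 35 with the filter on every array, 31 without a variance trend, 115 with all 10 arrays in the fit, 154 at adjusted p under 0.10 and 84 with the percentile over detected probes. Leaving out arrays gave 26 to 306 (26 without vehicle replicate 2, 306 without vehicle replicate 1). The ISR median in C2C12 was 0.35 to 0.50 over the arrays left out and 0.40 with an estimated correlation, where the list did not pass (adjusted p = 0.297).

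In transgenic muscle the AP20187 count was 3964, 717 at 2-fold or more, and 7071 with untreated wild type as control, which adds genotype, injection and session. Leaving out arrays gave 1802 (vehicle replicate 2) to 3347. The ISR median was 1.22 to 1.46 over the arrays left out. With an estimated correlation, which cannot alter the median, the list did not pass (camera adjusted p = 0.106). Rpl6 reversed, from -0.37 to 0.037, with the mean over its probes, through a dim probe that the 3 others (-0.37 to -0.27) do not bear out.

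Transgenic vehicle against wild type gave 5184 genes, 1132 at 2-fold or more, 8639 with probes without a symbol and 3116 (without wild type replicate 1) to 5250 over the arrays left out. The difference between muscle and C2C12 gave 1790 genes, 665 at 2-fold or more, and 1082 (without transgenic vehicle replicate 2) to 1643 over the arrays left out.

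Genes shared in direction numbered 11, and 55 with normexp, 18 with quantile normalization, 26 without a filter, 3 without a variance trend, 25 with all 10 arrays in the fit, 39 at adjusted p under 0.10 and 20 with the percentile over detected probes. Leaving out arrays gave 7 (transgenic vehicle replicate 2, C2C12 vehicle replicate 2) to 42 (C2C12 vehicle replicate 1), with 17 and 28 without C2C12 AP20187 replicate 1 and 2. The correlation of 0.0046 was -0.074 without a filter, 0.077 with the filter on every array and -0.036 to 0.044 over the arrays left out.

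With a replicate block the counts were 5593 in muscle, 106 in C2C12, 6428 for transgenic vehicle against wild type, 2606 for the difference and 23 shared. The replicates share only a number, and the replicate differences of paired groups correlated at 0.049 to 0.202, so that this block is no better grounded than the unpaired fit. A slide block could not be fitted, since slide or session coincides with the groups compared or is the same for them.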

Other observations

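The genes of this part were picked after their values were seen, and no test was added for them; the matched random lists were likewise chosen only then.

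NRF2 targets moved in both directions with AP20187 in transgenic muscle: 6 of 20 rose and 7 fell (8 and 9 adjusted over the list alone), so that the list did not pass (camera adjusted p = 0.611). Srxn1 rose by 2.72, Nfe2l2 by 1.41, Hmox1 by 1.32, Gclc by 1.14 and Txnrd1 by 1.01 log2 units. The glutathione transferase genes Gsta3 (-2.05), Gsta4 (-1.09) and Gstm1 (-0.64) and the thioredoxin gene Txn1 (-0.54) fell.

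Within the ISR list, Atf4, Ddit3 and Atf3 were already higher in transgenic vehicle than in wild type, by 1.53, 1.93 and 2.03, while Ddit4 (-1.61) and Vldlr (-0.55) were lower. Psat1 and Atf5, far above wild type in transgenic vehicle, did not pass with AP20187 (-0.19 and 0.03), except for Atf5 after quantile normalization (0.26).

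Of 14 measured denervation genes, 4 had a higher AP20187 change in muscle than in C2C12, Ankrd1 (1.94), Runx1 (2.27), Musk (1.14) and Dok7 (1.27), and 0 a lower change. The median difference of the list was 0.23 (camera adjusted p = 0.0489). It did not pass with an estimated correlation (adjusted p = 0.242), after quantile normalization (0.0726) or with outlier spots kept (0.0611).

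Against 10000 random lists matched on mean signal, a comparison that restates the camera result, the ISR medians lay above the highest random median in transgenic vehicle against wild type (1.46 against 0.76), with AP20187 in muscle (1.22 against 0.32) and in C2C12 (0.40 against 0.11), as did the adipocyte median in C2C12 (2.87 against 0.68). Random lists take no account of correlation between members. With an estimated correlation none of the 4 passed (camera adjusted p = 0.254, 0.106, 0.297 and 0.297, in the same order).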
